A study of Mus musculus with 44 samples.

How the data were processed

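RNA was measured in 44 libraries of mouse peritoneal macrophages. The cells came from C57BL/6 mice, were drawn to the peritoneum with thioglycolate, collected 4 days later, pooled from several mice into 1 isolate, and kept as adherent cells in DMEM with 10% FBS. Cultures received no stimulus, an extract of H9c2 cells (10 µg/mL), IL-4 (10 ng/mL) or LPS (100 ng/mL), and RNA was taken with Trizol after 8, 24 or 72 h. Replicates are therefore cultures of 1 isolate, and every p-value measures only the spread between these cultures, not between animals. Libraries were made from polyadenylated RNA with the Diagenode CATS mRNA-seq v2 kit and read from 1 end at 50 bp, per the labels' protocols.

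The deposited values are counts: whole-number reads per Ensembl gene, for 46078 genes and 5 summary entries, in 1 table of the whole series. Per the submitters' processing notes, cutadapt, Bowtie2, TopHat2 2.1.1, TopHat, HTSeq, DESeq and edgeR were used with build mm10. The annotation release and the strand setting of the counting are not given in the sources used here. Reads of overlapping or antisense genes, such as Il1b and Il1bos, Cxcl10 and Art3, or Mrc1 and Mir511, therefore cannot be told apart, and those genes' levels are uncertain to that extent, as are members of near-identical families such as H2-Q6 and H2-Q7, the Ifit3, Gbp and Ly6 genes and Stfa3. The summary entries stayed out of library sizes and tests, and reads in the ambiguous entry made up 5.39% of the sum of gene counts and ambiguous reads over all libraries (3.16% to 17.3% per library). Alignments that were not unique numbered 41.7 to 92.8 per 100 gene counts. Symbols and positions came from GENCODE M21 (GRCm38, the assembly that mm10 denotes), in which 45143 of the Ensembl identifiers were found and 935 were not.

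The table was analysed with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0 in R 4.3.3. Genes were kept where filterByExpr with a minimum count of 10 passed them over the 12 groups, which left 14537. Libraries were scaled by TMM, and 1 quasi-likelihood model with a coefficient per group was fitted to all 44 libraries, so that the groups share 1 estimate of the spread (common biological coefficient of variation 0.219, 32 residual degrees of freedom). A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within a comparison. Fold changes and their standard errors are on the fitted log2 scale with a prior count of 0.125. Levels are TMM-scaled counts per M (CPM), as mean ± SD over cultures. Where all libraries of a group had 0 counts, the fold is given as a lower bound against a floor of 3 counts over that group, and where a group had 1 to 3 counts the levels and counts are given without a fold. Such floors cover counting error only, since reads without molecular identifiers are not independent molecules.

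Comparisons were each stimulus with control at the same time, cell extract with LPS at the same time, control at 72 h with control at 8 h, and for each stimulus its effect at 72 h minus its effect at 8 h. The design, the alternatives, 33 gene lists (632 entries, 612 distinct symbols, of which 2 were not found) and the rule for named genes were fixed before the data were examined. Lists with at least 5 tested members, 31 of the 33, were tested with camera at a preset correlation between genes of 0.01, adjusted over the lists within a comparison, and again with an estimated correlation. The estimated correlation is the stricter test here, and calls lost under it are counted in every comparison, with that p for each in those with control. Among called lists, the median, the mean and the test differed in sign for clearance of dead cells in the IL-4 effect difference.

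The rule for named genes was this. Among genes with an adjusted p under 0.05, a mean of at least 1 CPM over the libraries of both groups and every library of the stimulated group on the same side of every control library, it took the 8 largest rises and 5 largest falls for cell extract, and 5 and 3 for LPS and for IL-4. The same condition gave 5 and 5 for cell extract against LPS, for control at 72 h against 8 h and for each effect difference, there without the condition on every library. From each fixed list it took up to 4 tested members with the smallest p, whichever way they moved, and always Nos2, Il1b, Il6, Tnf, Il12b, Cxcl10, Arg1, Chil3, Retnla, Mrc1 and Ccl17. Where the text would pass about 30 genes, names were to be left out from the end of that order. In a departure from that order, the 11 genes named always were kept in every comparison, and the list members were reduced instead, to 1 to 3 per list for some lists. Some list members are not reported here. Always-named genes left out of an earlier selection because they were mostly not called were put back.

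Alternatives were RLE size factors, a DESeq2 Wald test, no filter on low counts, a fit of the compared groups alone, the replicate number as a block, and each library left out in turn. For lists, an estimated correlation and a test on DESeq2 statistics were added to these, and for correlations a minimum of 10 CPM and controls split between the comparisons. A pair of further alternatives was added after seeing the data: leaving out 7 libraries with at least 5% of counts on rRNA-like genes, all of them replicate 3, and leaving out 5 libraries with under 2 M counts. Replicate numbers come from the sample titles, and no label says what a number shares. Deviations from group means of same-numbered libraries correlated above 0.1 in every pair against control for cell extract at 8 h (0.116 to 0.594). The same held for LPS at 8 h (0.118 to 0.508) and 24 h (0.119 to 0.585). Only these were taken as paired, though cell extract at 72 h also passed (0.249 to 0.284, 2 pairs).

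For counts of calls, all other splits of the same libraries into groups of the same sizes were fitted. For the effect differences, libraries were reshuffled within each time, first in 40 splits each and then in 100, and the number was raised after the counts of the first draw had been seen, so both draws are given.

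Simulated counts were built like the comparison of cell extract and control at 8 h (14336 genes tested). The test recovered 34%, 69.4%, 94% and 100% of genes changed 1.5-fold, 2-fold, 4-fold and 8-fold. Of its 153 calls 5 were unchanged genes. For the simulated effect difference of cell extract, recovery was 6%, 34.7%, 84% and 84% at those sizes. camera called the raised and the lowered list and 0 of 200 random lists. Random lists cannot show false calls on genes that move together. With libraries relabelled, up to 14 lists were called for cell extract at 8 h (real 12).

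No replicate pair agreed within sampling noise (chi-square per degree of freedom 3.57 to 219.5), so no library was counted as a copy of another.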

Results

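The series measured messenger RNA in mouse macrophages that were drawn to the peritoneum with thioglycolate, cultured, and then left unstimulated or given 1 of 3 stimuli for 8, 24 or 72 h. The stimuli were an extract of H9c2 cells, a cell line derived from rat heart, lipopolysaccharide (LPS), a bacterial product that drives classical (M1) activation, and interleukin 4 (IL-4), which drives alternative (M2) activation. By the series' title, the question was how damage-associated molecular patterns relate to M1 polarization. Each of the 12 groups had 4 libraries, except cell extract at 24 h and at 72 h, control at 72 h and IL-4 at 72 h, which had 3. Gene counts per library ran from 0.908 to 26.6 M (M, mega), and the groups were not equally deep. Group medians ran from 2.42 M (IL-4 at 8 h) to 15.9 M (IL-4 at 72 h), with 9.09, 9.10 and 2.86 M for the controls. Below, n is 4 unless stated, levels are mean ± SD in CPM, and adjusted p values are those of edgeR's quasi-likelihood test for genes and of camera for lists. A gene that did not pass is not thereby unchanged. Where it passed in a fit of the groups alone or with no filter on low counts, this is said. Passing with no filter is weak support, since with IL-4 at 8 h it included genes whose falls rested on control 8 h replicate 1.

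The first principal component of the 14537 tested genes, with 31.2% of the variance, set LPS libraries highest and cell extract libraries next, with those of IL-4 and control intermixed.

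**Figure D1:**
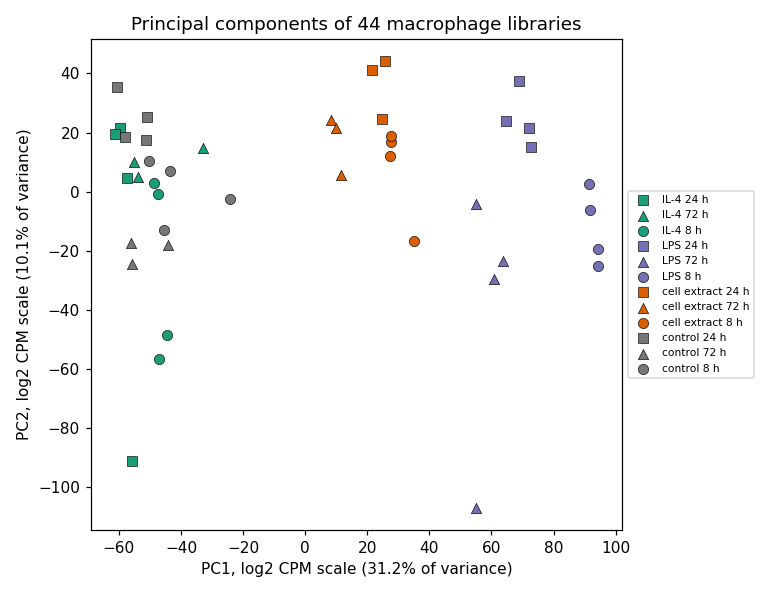
Each point is 1 of the 44 libraries, placed by its scores on the first (x, 31.2% of variance) and second (y, 10.1%) principal component of log2 CPM. On the x axis, the group means at 8 h are 93.0 for LPS, 29.4 for cell extract, -40.9 for control and -46.9 for IL-4.

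LPS at 8 h raised interferon-stimulated genes, chemokines and named cytokines. The cytokine Il6 rose 118-fold (3217 ± 372 against 27.2 ± 49.2 CPM; log2 6.88 ± 0.891, SE; edgeR adjusted p = 1.99e-08), Il1b rose 104-fold, Tnf 95.9-fold and Il12b 98.4-fold. Cxcl10, an interferon-induced chemokine, rose 109-fold, and Nos2, the inducible nitric oxide synthase of M1 macrophages, rose 73.5-fold. All 38 tested interferon-stimulated genes rose (38 adjusted over the list alone; camera adjusted p = 5.64e-50), among them Oasl2 (30.9-fold; edgeR adjusted p = 4.34e-23) and Irgm1 (16.8-fold; adjusted p = 2.24e-23). Genes of MHC class I presentation rose in 17 of 17 cases (17; camera adjusted p = 4.66e-14), with Tap1, a peptide transporter, up 12.9-fold. The chemokine Ccl12 rose 178-fold. Control 8 h replicate 1 held higher levels of LPS-induced genes than the other 3 controls, which lowers these folds, and without that library the log2 change of Il6 was 10.37 and that of Ccl12 11.74.

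Of the M1 list, 27 of 28 rose (27 adjusted over the list alone), and of the NF-kB list 24 of 24 rose (24 adjusted over the list alone), with the signalling adaptor Traf1 up 31.2-fold. Neutrophil- and monocyte-attracting chemokines rose in 12 of 14 cases (12; camera adjusted p = 2.02e-08). BC023105 had no read in the controls and was at least 108-fold higher. Olfr56 stood at 11.5 ± 2.85 against 0.0477 ± 0.0955 CPM (2 counts in the controls), Gm5970 at 14.3 ± 1.88 against 0.0716 ± 0.143 CPM (3 counts) and Tnfsf4 at 8.65 ± 2.19 against 0.0324 ± 0.04502 CPM (2 counts). Among the falls were Arhgap19 (51.99-fold), Galnt9 (32.3-fold), the cytosolic enzyme Idh1 (12.8-fold) and the sterol reductase Dhcr7 (8.77-fold), and Fut7 stood at 0.02904 ± 0.0581 against 3.34 ± 0.6995 CPM (1 count in LPS). Of the cholesterol list 12 of 22 fell and 3 rose (13 and 3 adjusted over the list alone), and the list was not called (camera adjusted p = 0.0574). The M2 markers Arg1 (log2 -0.08), Chil3 (0.39), Retnla (-0.01) and Mrc1 (-0.26) did not pass the test, and Ccl17 rose 9.49-fold. Of 14537 genes, 3099 rose and 3506 fell, 1822 and 1845 of them at least 2-fold, but 3307 rose and 3302 fell under RLE scaling. Of 31 lists, 9 were called, all upward, and 6 held with an estimated correlation. Lost with it were Toll-like receptor signalling (camera adjusted p = 0.131 with an estimated correlation), matrix remodelling (0.0681) and anti-inflammatory feedback (0.128).

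At 24 h of LPS the interferon-stimulated genes were again high. All 38 rose (38 adjusted over the list alone; camera adjusted p = 1.39e-61), with the GTPases Igtp up 35.5-fold and Tgtp1 up 694-fold. Gbp11, Apol9b, Gm5970 and Olfr56 had no read in the controls and were at least 222-fold, 136-fold, 131-fold and 103-fold higher. Genes of MHC class II presentation rose in 9 of 11 cases (9 adjusted over the list alone; camera adjusted p = 3.54e-06), with their transactivator Ciita up 10.3-fold, and all 17 of MHC class I rose (17 adjusted over the list alone), H2-Q6 by 34.9-fold. Clearance of dead cells moved the other way, in that 14 of 19 fell and 4 rose (14 and 4; camera adjusted p = 4.88e-05). The receptor Cd93 fell 11.5-fold.

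Nos2 rose 256-fold at 24 h (586 ± 58.3 against 2.81 ± 2.75 CPM; log2 8.00 ± 0.564, SE; edgeR adjusted p = 3.36e-15), Cxcl10 178-fold, Il1b 59.96-fold, Il12b 50.1-fold, Tnf 43.4-fold and Il6 23.5-fold. Control 24 h replicate 1 lowers these folds, and without it the log2 changes were 8.66, 8.47, 6.42, 6.31, 6.00 and 5.64. Of the M1 list 27 of 28 rose (28 adjusted over the list alone), and of the NF-kB list 23 of 24 rose (23 adjusted over the list alone). Of the chemokines 11 of 14 rose and 1 fell (12 and 1 adjusted over the list alone; camera adjusted p = 0.108 with an estimated correlation). The mannose receptor Mrc1 fell 10.4-fold. Arg1 (log2 0.68; edgeR adjusted p = 0.0857), Chil3 (log2 -1.23; adjusted p = 0.0591) and Retnla (log2 -0.97; adjusted p = 0.334) did not pass the test. Ccl17 was at least 11.7-fold higher (0.988 ± 0.858 CPM, no read in the controls). Mamdc2 fell 75.4-fold and Cmbl 46.3-fold, and Gpm6a stood at 0.0194 ± 0.0387 against 2.67 ± 0.6299 CPM (1 count in LPS). 2705 genes rose and 2809 fell. Of the 15 lists called, 12 rose and 3 fell, and 7 held with an estimated correlation. Besides the chemokines, those lost were Toll-like receptor signalling (camera adjusted p = 0.206 with an estimated correlation), glycolysis (0.296), oxidative stress response (0.159), matrix remodelling (0.167), monocyte markers (0.0765), LXR targets (0.111) and cholesterol synthesis (0.159). Of the last 10 of 22 fell and 1 rose (10 and 1 adjusted over the list alone), with Sqle, squalene epoxidase, down 2.36-fold. With no filter Arg1, Retnla and Chil3 passed (edgeR adjusted p at most 0.00886). Leave-one-out fits passed Arg1 without control 24 h replicate 3 (edgeR adjusted p = 0.0071) or LPS 24 h replicate 1 (0.0494) or 2 (0.0406) and Chil3 without control 24 h replicate 2 (0.0213) or 4 (0.0232) or LPS 24 h replicate 1 (0.0284).

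At 72 h of LPS, glycolysis and MHC class II genes rose while clearance, cholesterol and cell cycle genes fell. Of the glycolysis list 17 of 19 rose (17 adjusted over the list alone; camera adjusted p = 1.54e-15), with the glucose transporter Slc2a1 up 4.26-fold (n = 3 for control at 72 h throughout) and Ldha, lactate dehydrogenase, up 3.59-fold. MHC class II presentation rose in 10 of 11 genes (10; camera adjusted p = 1.15e-11), with H2-Ab1 up 9.18-fold and Cd74 8.22-fold. Of clearance of dead cells 13 of 19 fell and 3 rose (13 and 3 adjusted over the list alone; camera adjusted p = 9.52e-11), with the bridging protein Gas6 down 18.2-fold and complement C1qb 9.71-fold. Of cholesterol synthesis 18 of 22 fell (18), with Cyp51, a sterol demethylase, down 3.91-fold. The list's mean sum rose in control from 1038 CPM at 24 h to 1662 at 72 h, against 754 and 686 with LPS. Of the cell cycle list 23 of 31 fell and 1 rose (24 and 1), with cyclin Ccnb2 down 11.2-fold.

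Nos2 stayed high at 72 h (574 ± 209 against 5.17 ± 3.67 CPM; 129.9-fold; edgeR adjusted p = 8.61e-12), and Il1b rose 67.9-fold, Cxcl10 20.03-fold, Il12b 16.1-fold and Tnf 12.4-fold. Il6 did not pass the test (log2 2.44; edgeR adjusted p = 0.0671), but did in these groups alone (0.00485) and with no filter (8.72e-17). Of the M1 list 25 of 28 rose (27 adjusted over the list alone), and of the NF-kB list 20 of 24 rose (20). All 38 interferon-stimulated genes rose (38). Monocyte markers rose in 7 of 13 cases (7; camera adjusted p = 0.0124), with Ly6c2 up 480.4-fold, and Ly6i rose 473-fold. The serotonin receptor Htr7 and Gbp11 had no read in the controls and were at least 85.5-fold and 60.6-fold higher, and Ubd stood at 162 ± 21.5 against 0.3197 ± 0.282 CPM (3 counts in control). Mrc1 fell 10.3-fold, while Arg1 (edgeR adjusted p = 0.522), Chil3 (0.735), Retnla (0.688) and Ccl17 (0.178, 5 counts in LPS and 0 in control) did not pass the test. Markers of mesothelial cells and fibroblasts were lower: 15 of 17 fell (15 adjusted over the list alone; camera adjusted p = 5.58e-15), with Upk3b, a mesothelial gene, down 243-fold. Tceal7 stood at 0.0458 ± 0.0915 against 8.05 ± 2.66 CPM and Nkain4 at 0.0458 ± 0.0915 against 5.79 ± 0.416 CPM (1 count each in LPS), and the smooth muscle actin Acta2, of the muscle list, fell 27.6-fold. These markers were higher in control at 72 h than at 8 h, as given below. 2344 genes rose and 2232 fell, but 2194 rose and 2415 fell under RLE scaling. Of 31 lists 13 rose and 6 fell, of which 15 held with an estimated correlation, and chemokines (camera adjusted p = 0.288 with an estimated correlation), Toll-like receptor signalling (0.189), oxidative stress response (0.252) and matrix remodelling (0.0976) did not. A fit of these groups alone called 2787 genes, and the call of Il12b was lost without control 72 h replicate 1 (edgeR adjusted p = 0.0556).

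**Figure D2:**
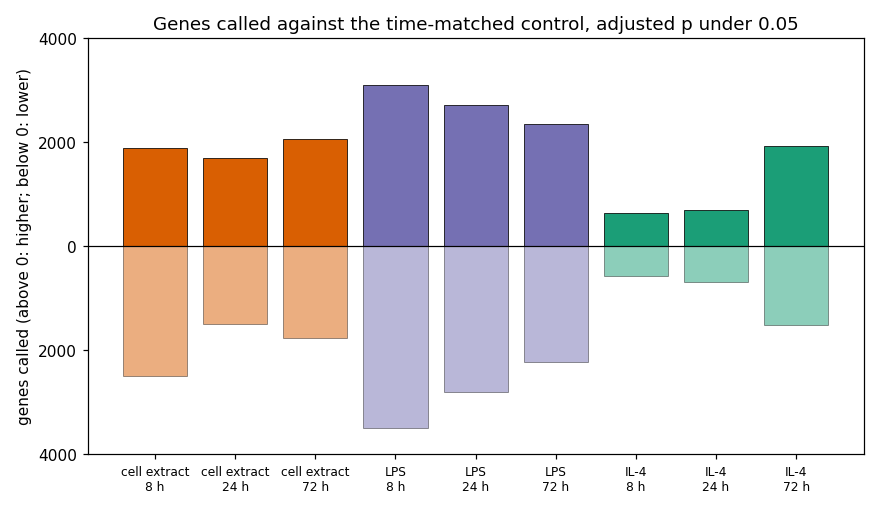
Genes called higher (up) and lower (down) at an adjusted p under 0.05 for each comparison with control, by stimulus and time, out of 14537 tested genes. LPS gave the most calls at each time, from 3099 higher and 3506 lower at 8 h to 2344 and 2232 at 72 h, and IL-4 the fewest, from 624 and 587 to 1914 and 1527. In fits of the groups alone the order at 72 h differs, with 3578 calls for cell extract and 2787 for LPS.

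IL-4 at 8 h raised the M2 list, in which 26 of 30 rose and 0 fell (27 and 1 adjusted over the list alone; camera adjusted p = 4.56e-71). Arg1, the arginase of alternative activation, rose 88.6-fold (1466 ± 290.2 against 16.6 ± 2.43 CPM; log2 6.47 ± 0.381, SE; edgeR adjusted p = 5.77e-16), the chitinase-like Chil3 17.8-fold, Retnla 12.1-fold and Mrc1 3.98-fold. The ligand Pdcd1lg2 rose 101-fold, and the transcription factor Irf4 25.02-fold. Mrgprg had no read in the controls and was at least 95.5-fold higher, and the adipokine Adipoq stood at 8.06 ± 0.151 against 0.0437 ± 0.0528 CPM (3 counts in control) and Il31ra at 4.81 ± 2.51 against 0.01705 ± 0.0341 CPM (2 counts). Of Toll-like receptor signalling 5 of 21 fell and 0 rose (11 and 1 adjusted over the list alone; camera adjusted p = 0.364 with an estimated correlation), with Tlr13 down 3.56-fold and Tlr2 2.73-fold. Cxcr1 fell 8.16-fold, Slc40a1, the iron exporter, stood at 0.107 ± 0.214 against 2.84 ± 0.564 CPM (3 counts in IL-4) and Gm13012 at 0.241 ± 0.218 against 1.93 ± 0.697 CPM (3 counts). The M1 list was not called (camera adjusted p = 0.774). Nos2 (log2 -0.44), Il1b (-1.49), Tnf (-1.55), Il6 (-1.81), Il12b (-2.66), Cxcl10 (-1.97) and Ccl17 (2.15) did not pass the test, with edgeR adjusted p from 0.0688 to 0.72. With no filter Il1b, Tnf, Il6, Il12b and Cxcl10 passed (edgeR adjusted p at most 1.18e-06). The high controls of these genes come from replicate 1, without which Nos2, Il1b, Tnf, Il6, Il12b and Cxcl10 stood at 0.85, 1.05, 0.30, 1.67, 0.03 and 1.25, none passing. 624 genes rose and 587 fell, 281 and 157 at least 2-fold. Of the 6 lists called, only M2 held with an estimated correlation, and those lost also include unfolded protein response (camera adjusted p = 0.0603 with an estimated correlation), anti-inflammatory feedback (0.0901), whose member Socs1 rose 13.6-fold, matrix remodelling (0.347) and immediate early genes (0.347). Without control 8 h replicate 1, 14 lists were called, and a fit of these groups alone called 615 genes. Leave-one-out fits passed Ccl17 without control 8 h replicate 1 (edgeR adjusted p = 0.0259) and Il12b without control 8 h replicate 2 (0.0425).

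At 24 h of IL-4, genes of the M2 list, the unfolded protein response and MHC class II were higher than in control. Of the M2 list 26 of 30 rose and 1 fell (27 and 1 adjusted over the list alone). Chil3 rose 56.3-fold to 13593 ± 1799 CPM from 241 ± 249.7 (edgeR adjusted p = 7.51e-09), Retnla 114-fold, Arg1 70.6-fold, Mrc1 2.63-fold and the signalling inhibitor Cish 67.3-fold. The chemokine Ccl17 had no read in the controls and was at least 41.5-fold higher, and the ribonuclease Rnase2a rose 111-fold. Of the unfolded protein response list 11 of 17 rose and 0 fell (14 and 1 adjusted over the list alone; camera adjusted p = 1.99e-14), with the chaperones Pdia4 up 4.42-fold and Hspa5 1.95-fold. Of MHC class II 6 of 11 rose (6), with Ciita up 3.65-fold. Of the respiratory chain list 11 of 32 rose (12 adjusted over the list alone; camera adjusted p = 2.25e-08, or 0.0425 with an estimated correlation), with Cyc1 up 1.82-fold.

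Irf4 remained up 11.9-fold at 24 h, and Adipoq stood at 5.84 ± 2.81 against 0.0617 ± 0.123 CPM (1 count in control) and Col6a5 at 9.65 ± 2.45 against 0.1101 ± 0.102 CPM (3 counts). The adrenergic receptor Adra1a fell 7.65-fold, Gpr162 10.8-fold and Fcrl1 6.16-fold. Of the M1 list, 1 of 28 members rose, Nos2 (3.83-fold, or log2 2.60 without control 24 h replicate 1; edgeR adjusted p = 0.0153). Il1b, Tnf, Il6, Il12b and Cxcl10 did not pass the test (log2 -0.43, -0.61, -0.62, -1.02 and -0.31). Their direction is open, since the mean levels of all but Tnf run the other way (Cxcl10 8.32 ± 11.9 against 5.49 ± 6.39 CPM) with the high replicate 1 of IL-4. The log2 changes were -1.07, -1.25, -1.15, -1.73 and -1.0 without it, and 0.09, -0.04, 0.47, -0.36 and 0.69 without control 24 h replicate 1. 689 genes rose and 692 fell. Of the 13 lists called, 10 rose and 3 fell, and 5 held with an estimated correlation. Lost with it were chemokines (camera adjusted p = 0.263 with an estimated correlation), Toll-like receptor signalling (0.269), MHC class I (0.468), clearance of dead cells (0.263), cell cycle (0.269), the p53 response (0.263), heat shock (0.162) and dendritic cell markers (0.101). Without the rRNA-rich libraries calls were lost for Nos2 (edgeR adjusted p = 0.0933) and in these groups alone for Cyc1 (0.0586). Calls lost with 1 library fewer were Nos2 without control 24 h replicate 2 (edgeR adjusted p = 0.0729), 3 (0.0774) or 4 (0.0565).

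By 72 h of IL-4, Chil3 stood at 39769.6 ± 7616 CPM against 207 ± 122 in control (n = 3 in both groups), 193-fold higher (edgeR adjusted p = 1.28e-09). Retnla rose 84.1-fold, Arg1 10.05-fold, the transglutaminase Tgm2 8.89-fold and Mrc1 4.03-fold, and of the M2 list 21 of 30 rose and 2 fell (23 and 2 adjusted over the list alone), F13a1 falling 11.5-fold. The rise of Retnla was not shared by IL-4 72 h replicate 3, at 13.2 CPM against 12.8 in control 72 h replicate 3. IL-4 72 h replicates 2 and 4 stood at 853.8 and 778.2 CPM. Mrc1 was also lower in that replicate 3 (521.1 CPM, against 1219.8 and 1142.9). Rnase2a, Gprc6a and Pgm5 had no read in the controls and were at least 84.8-fold, 31.5-fold and 8.53-fold higher, and RP23-191E1.1 stood at 11.03 ± 3.59 against 0.119 ± 0.205 CPM (1 count in control). Of the unfolded protein response list 7 of 17 rose and 2 fell (8 and 3; camera adjusted p = 0.00067). Asns, asparagine synthetase, rose 5.98-fold and Trib3 5.61-fold. Of cholesterol genes 19 of 22 fell (19; camera adjusted p = 4.93e-30), with Cyp51 down 4.54-fold. Of the cell cycle list 19 of 31 fell and 1 rose (21 and 1), with Ccnb2 down 7.71-fold.

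Mesothelial and fibroblast markers were lower in 11 of 17 cases (13 adjusted over the list alone; camera adjusted p = 2.64e-18). Muscle markers were lower in 5 of 10 (5), with Acta2 down 32.4-fold. C1qb fell 6.33-fold, Sdpr 58.3-fold, Fgf18 stood at 0.0126 ± 0.0219 against 2.02 ± 0.376 CPM (1 count in IL-4) and Gm26175 at 0.0466 ± 0.0807 against 2.26 ± 3.28 CPM (2 counts). Ccl17 (22 counts in IL-4 and 0 in control; edgeR adjusted p = 0.0576), Nos2 (log2 0.06, with means of 4.69 ± 1.79 against 5.17 ± 3.67 CPM), Il1b (-1.17), Il6 (-0.999), Tnf (-0.24), Il12b (-1.27) and Cxcl10 (-1.99) did not pass the test. Cxcl10 passed in these groups alone (edgeR adjusted p = 0.0176), and with no filter Cxcl10, Il1b and Il6 passed (at most 0.0477). 1914 genes rose and 1527 fell, but 1398 rose and 1910 fell under RLE scaling. Of the 11 lists called, 4 rose and 7 fell, and 6 held with an estimated correlation, those lost being MHC class I (camera adjusted p = 0.488 with an estimated correlation), clearance of dead cells (0.0541), anti-inflammatory feedback (0.367), neutrophil markers (0.0694) and B cell markers (0.0541). Gm26175 lost its call without control 72 h replicate 3 (edgeR adjusted p = 0.519) or IL-4 72 h replicate 2 (0.0924) or 4 (0.0766) or with DESeq2 (0.0538).

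**Figure D3:**
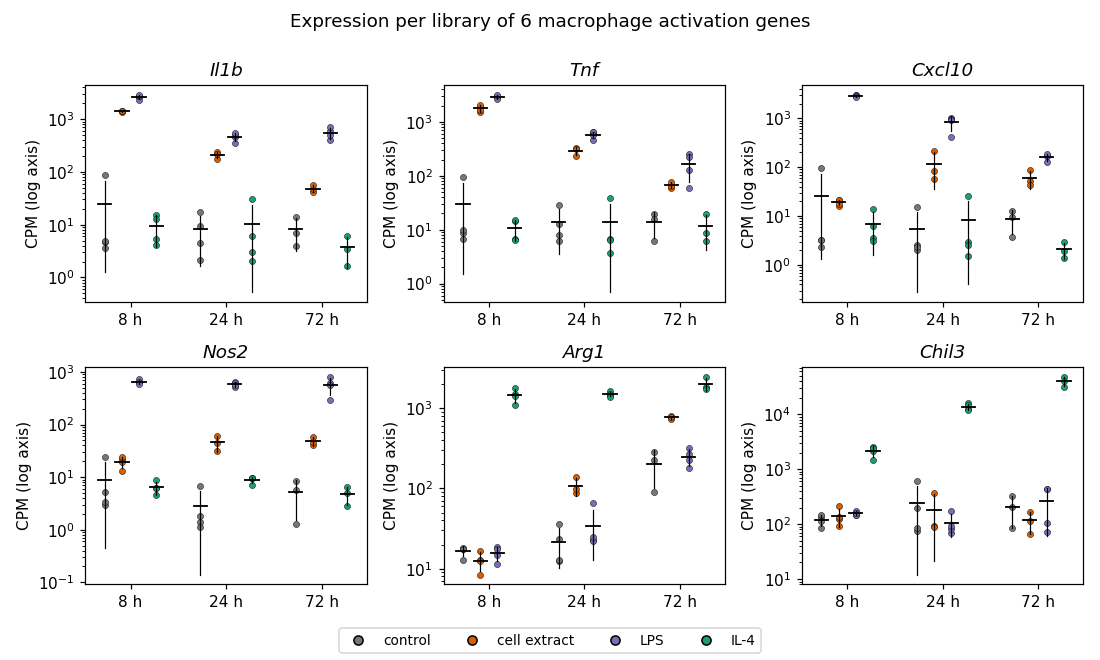
Levels in CPM (log axis) of 6 of the genes named in every comparison, by stimulus and time. Points are libraries and bars are mean ± SD, with lower bars that would pass 0 drawn short.

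Cell extract at 8 h raised NF-kB targets, several chemokines and cytokines and, less than LPS did, some interferon-stimulated genes. The neutrophil-attracting chemokines Cxcl3, Cxcl1 and Cxcl2 rose 282-fold (889.7 ± 87.6 against 3.09 ± 2.75 CPM; log2 8.14 ± 0.789, SE; edgeR adjusted p = 5.1e-11), 154-fold and 144-fold. Tnf rose 58.1-fold, Il1b 56.4-fold, Il12b 18.1-fold and Il6 8.29-fold. The receptors Gpr84 and Fpr1 rose 92.96-fold and 63.4-fold, and Gm37549 50.3-fold. All 24 genes of the NF-kB list rose (24 adjusted over the list alone; camera adjusted p = 3.23e-46), with Malt1 up 9.08-fold, and of the M1 list 22 of 28 rose (23 adjusted over the list alone).

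Of 38 interferon-stimulated genes, 15 rose and 3 fell (15 and 6 adjusted over the list alone; camera adjusted p = 6.01e-05, or 0.542 with an estimated correlation), with Gbp2 up 8.47-fold and Irgm1 3.13-fold. Without control 8 h replicate 1 the counts were 23 and 1, with a median log2 change of 0.81. That library also lowered the log2 changes of Tnf (7.71 without it), Il1b (8.36), Il6 (6.54), Il12b (6.87) and Nos2 (2.45), the last 2.23-fold higher with it (edgeR adjusted p = 0.0372). Cxcl10 was 19.1 ± 2.59 against 26.3 ± 46.8 CPM (log2 -0.46; edgeR adjusted p = 0.728), but without that library its log2 change was 2.76 (adjusted p = 0.000549). Ccl17 rose 3.42-fold (edgeR adjusted p = 0.0415). Nos2 lost its call without control 8 h replicate 2 (edgeR adjusted p = 0.177), 3 (0.0859) or 4 (0.146) or cell extract 8 h replicate 1 (0.0762) or 4 (0.0944), and Ccl17 without control 8 h replicate 2 (0.192), 3 (0.0795) or 4 (0.0533) or cell extract 8 h replicate 2 (0.13) or 4 (0.126). Without the rRNA-rich libraries calls were lost for Nos2 (edgeR adjusted p = 0.0725), in these groups alone for Nos2 (0.123), with no filter for Ccl17 (0.134) and with DESeq2 for Ccl17 (0.0509).

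The oxidative stress response to Nrf2 rose, in that 15 of 21 rose and 2 fell (15 and 2 adjusted over the list alone; camera adjusted p = 2.02e-14), with the cystine transporter Slc7a11 up 35.5-fold and Gclm, of glutathione synthesis, 5.796-fold. Of cholesterol synthesis and uptake 15 of 22 rose and 1 fell (17 and 1 adjusted over the list alone; camera adjusted p = 7.26e-07), with Hsd17b7 up 3.69-fold, while Dhcr7 fell 3.08-fold. Of Toll-like receptor signalling 8 of 21 rose and 4 fell (9 and 4 adjusted over the list alone; camera adjusted p = 0.147 with an estimated correlation), with Tlr2 up 21.6-fold and the LPS co-receptor Cd14 8.74-fold. Clearance of dead cells fell in 13 of 19 genes (13; camera adjusted p = 0.000592, or 0.0499 with an estimated correlation). The integrin Itgb5 fell 3.901-fold. Of the M2 list 8 of 30 rose and 7 fell (8 and 7 adjusted over the list alone; camera adjusted p = 0.573), with the amino acid transporter Slc7a2 up 15.9-fold and the nuclear receptor Pparg down 4.23-fold. Arg1, Chil3, Retnla and Mrc1 did not pass the test (log2 -0.41, 0.22, -0.27 and -0.15). Other falls were the ubiquitin ligase gene Fbxo32 (15.4-fold), Cmbl (21.8-fold), Dppa3 (18.8-fold), RP23-297M4.7 (18.4-fold) and 2210011C24Rik (18.2-fold). 1892 genes rose and 2494 fell, 855 and 1051 at least 2-fold, but 2202 rose and 2138 fell under RLE scaling, and 11 lists rose and 2 fell, of which 9 held with an estimated correlation. MHC class I (camera adjusted p = 0.104 with an estimated correlation) and LXR targets (0.153) were among those lost.

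At 24 h of cell extract (n = 3) every tested interferon-stimulated gene was called: 38 of 38 rose (38 adjusted over the list alone; camera adjusted p = 1.07e-46), with Zbp1 up 15.2-fold and Gbp7 12.4-fold. Cxcl10 rose 25.7-fold (119 ± 83.3 against 5.49 ± 6.39 CPM; edgeR adjusted p = 4.49e-05), Nos2 20.1-fold, Il1b 27.5-fold, Il6 25.3-fold, Tnf 21.9-fold and Il12b 21.3-fold. Control 24 h replicate 1, with higher levels than the other controls, lowers these folds, and without it the log2 changes were 5.68, 4.99, 5.29, 5.75, 5.01 and 5.08. The formyl peptide receptors Fpr2 and Fpr1 rose 256-fold and 134-fold, the siderophore-binding Lcn2 128-fold and Gpr84 164-fold. Wfdc21 and Olfr56 had no read in the controls and were at least 67.1-fold and 35.4-fold higher. Siglece stood at 27.3 ± 1.86 against 0.0504 ± 0.0584 CPM and Gm37549 at 12.04 ± 2.82 against 0.0484 ± 0.0565 CPM (2 counts each in control). Arg1 also rose, 5.13-fold (edgeR adjusted p = 4.08e-07), while Mrc1 fell 2.51-fold.

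Of the M1 list 25 of 28 rose and 0 fell (26 and 1 adjusted over the list alone), and of the NF-kB list 24 of 24 rose (24 adjusted over the list alone), with Sod2 up 16.6-fold. Of the chemokine list 12 of 14 rose and 1 fell (12 and 1). Oxidative stress genes rose in 17 of 21 cases (18; camera adjusted p = 1.49e-20), with Slc7a11 up 21.6-fold and the quinone reductase Nqo1 9.88-fold. Cholesterol genes rose in 15 of 22 (16 adjusted over the list alone), with Lss up 1.89-fold, the unfolded protein response in 10 of 17 (11), with Hspa5 up 2.06-fold, and glycolysis in 9 of 19 (9; camera adjusted p = 0.204 with an estimated correlation), with Pfkl up 2.43-fold. Neutrophil markers rose in 4 of 7 cases (4; camera adjusted p = 1.1e-06). Among them the gelatinase Mmp9 rose 15.1-fold, and Camp stood at 2.05 ± 1.09 against 0.0268 ± 0.0535 CPM (1 count in control). Retnla and Chil3 did not pass the test (log2 0.11 and -0.39, or -1.51 and -1.42 without cell extract 24 h replicate 4). Upk3b fell 20.8-fold, Tceal7 31.2-fold, Cmbl 19.7-fold and Mrgprx2 18.5-fold, and Pcp4l1 stood at 0.0809 ± 0.1402 against 2.62 ± 0.799 CPM (3 counts in cell extract). 1700 genes rose and 1509 fell. Of the 16 lists called, 14 rose and 2 fell, and 11 held with an estimated correlation, the others lost being Toll-like receptor signalling (camera adjusted p = 0.155 with an estimated correlation), MHC class II (0.231), clearance of dead cells (0.0685) and mesothelial and fibroblast markers (0.307). Ccl17 had no read in the controls and was at least 2.14-fold higher (edgeR adjusted p = 0.0192). Ccl17 lost its call without control 24 h replicate 3 (edgeR adjusted p = 0.0531) or cell extract 24 h replicate 3 (0.0518) or with no filter (0.0552) or with DESeq2 (0.0626).

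At 72 h of cell extract (n = 3 in both groups) interferon-stimulated and MHC class I genes stayed up while cholesterol genes turned down. Of the interferon list 36 of 38 rose (36 adjusted over the list alone; camera adjusted p = 9.51e-32), with Oasl2 up 4.75-fold. Of MHC class I 13 of 17 rose (15), with H2-Q6 up 20.1-fold and H2-Q7 12.6-fold. The scavenger receptor Marco rose 54.5-fold (184 ± 3.76 against 3.94 ± 2.47 CPM; log2 5.77 ± 0.417, SE; edgeR adjusted p = 1.74e-13), Fpr1 93.3-fold, the transporter Slc13a3 66.3-fold, and the acute-phase genes Hp and Orm1 41.8-fold and 45.8-fold. Orm1 had 5 counts in control. The repair factors Serpinb2 and Tgfbi rose 34.4-fold and 26.6-fold, and of the matrix remodelling list 14 of 27 rose and 4 fell (15 and 4 adjusted over the list alone). Of the cholesterol list 20 of 22 fell (20; camera adjusted p = 3.49e-21), with Cyp51 down 3.79-fold and Hmgcs1 2.64-fold.

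Nos2 rose 10.9-fold at 72 h (48.5 ± 9.04 against 5.17 ± 3.67 CPM; edgeR adjusted p = 4.29e-05), Cxcl10 7.48-fold, Il1b 5.91-fold and Tnf 4.99-fold. Il6 (log2 1.51; edgeR adjusted p = 0.321) and Il12b (log2 2.90; adjusted p = 0.093) did not pass the test. Arg1 rose 3.85-fold and Mrc1 fell 2.25-fold, Chil3 and Retnla did not pass the test (log2 -0.83 and -1.91), and Ccl17 had no read in either group. Il12b and Retnla passed in these groups alone (edgeR adjusted p = 0.00588 and 0.0218), and with no filter these, Il6 and Chil3 passed (at most 0.0371). Gbp11 had no read in the controls and was at least 7.88-fold higher, and Hsd11b1 stood at 8.41 ± 0.223 against 0.119 ± 0.205 CPM and Arg2 at 7.68 ± 1.12 against 0.119 ± 0.205 CPM (1 count each in control). Of the M1 list 22 of 28 rose and 1 fell (24 and 1 adjusted over the list alone), and of the NF-kB list 16 of 24 rose (17 adjusted over the list alone). Glycolysis rose in 13 of 19 genes (13; camera adjusted p = 0.0637 with an estimated correlation), with the hexokinase Hk2 up 1.97-fold. Of the cell cycle list 21 of 31 fell (24; camera adjusted p = 2.11e-09), with Ccnb2 down 4.68-fold. Mesothelial and fibroblast markers were lower in 15 of 17 cases (15; camera adjusted p = 4.18e-16). Upk3b fell 314-fold, Lrrn4 118-fold and Col1a1 4.55-fold. Acta2 fell 17.1-fold and Tagln 18.4-fold, the immunoglobulin gene Ighm fell 4.38-fold, and Igfbp2, Slco2b1 and Nkain4 had 1 count each with cell extract, against 3.39 ± 2.07, 4.300 ± 0.501 and 5.79 ± 0.416 CPM in control. 2058 genes rose and 1769 fell, but 1841 rose and 2008 fell under RLE scaling. Of the 18 lists called, 11 rose and 7 fell, and 11 held with an estimated correlation, the others lost being chemokines (camera adjusted p = 0.395 with an estimated correlation), inflammasome (0.0833), Toll-like receptor signalling (0.106), clearance of dead cells (0.0892), oxidative stress response (0.151) and anti-inflammatory feedback (0.173). Cxcl10 lost its call without control 72 h replicate 1 (edgeR adjusted p = 0.109) or 4 (0.0531) or cell extract 72 h replicate 4 (0.0797), and Il1b without control 72 h replicate 1 (0.112) or 4 (0.0649) or cell extract 72 h replicate 4 (0.0564). Tnf lost its call without control 72 h replicate 1 (edgeR adjusted p = 0.102).

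**Figure D4:**
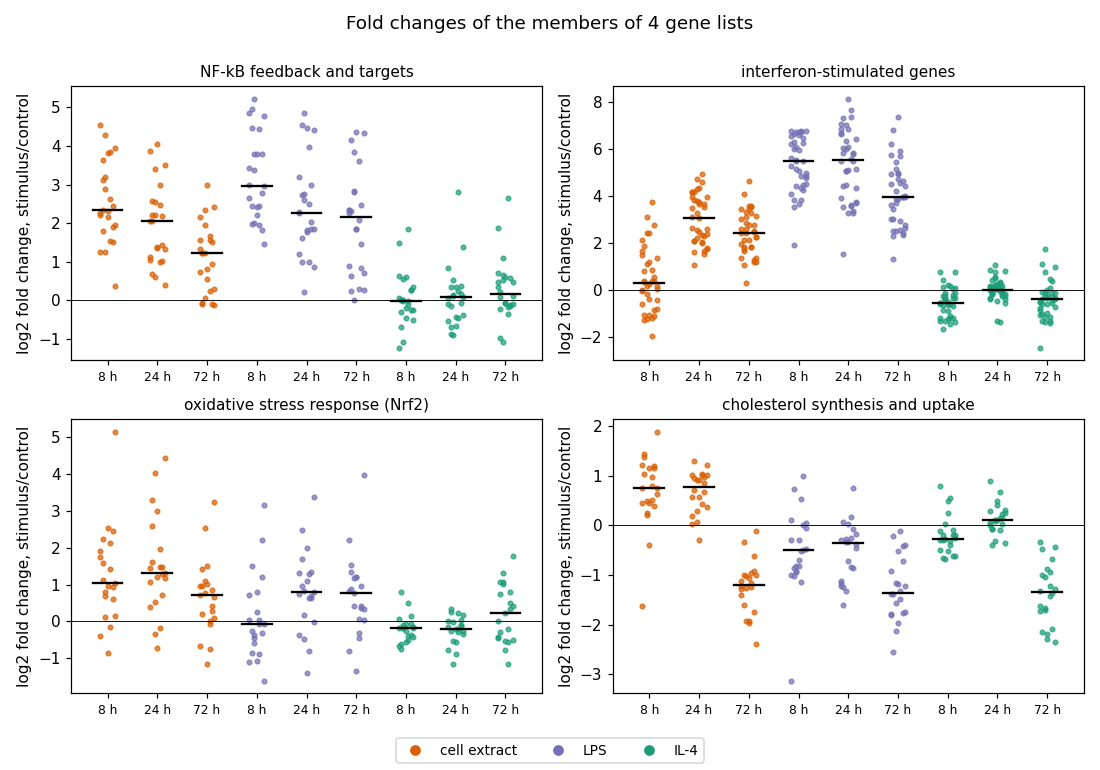
Log2 fold changes against control of the members of 4 gene lists, by stimulus and time, with the median of each list as a line. The median of the interferon-stimulated genes at 8 h is 0.28 with cell extract and 5.49 with LPS.

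Set directly against LPS at 8 h, cell extract gave lower interferon-stimulated genes and higher cholesterol and oxidative stress genes. All 38 interferon-stimulated genes were lower (38 adjusted over the list alone; camera adjusted p = 3.72e-70), with Cmpk2 248-fold lower, Ifit3 242-fold, Pydc4 247-fold, Ifit3b 295-fold and Gm14446 332-fold. All 17 MHC class I genes were lower (17). Cxcl10 was 149.8-fold lower, Nos2 32.9-fold, Il6 14.3-fold (226 ± 9.35 against 3217 ± 372 CPM; log2 -3.83 ± 0.769, SE; edgeR adjusted p = 0.00011), Il12b 5.43-fold and Ccl17 2.77-fold. Tnf (log2 -0.72; edgeR adjusted p = 0.369) and Il1b (log2 -0.89; adjusted p = 0.303) did not pass the test, but at similar folds both passed in these groups alone (0.000353 and 2.4e-06) and with no filter (0.013 and 0.00061). Arg1, Chil3, Retnla and Mrc1 did not pass (log2 -0.33, -0.17, -0.27 and 0.11). Cholesterol genes were higher in 18 of 22 cases (20; camera adjusted p = 2.92e-14) and oxidative stress genes in 15 of 21 (16; adjusted p = 1.43e-11). Kcnj2 (11.8-fold), Dnmt3l (13.1-fold), Aph1b (11.9-fold) and Mturn (11.3-fold) were higher, and Treml4 stood at 2.71 ± 0.944 against 0.1299 ± 0.152 CPM (3 counts in LPS). The M1 list was lower in 19 of 28 genes (20 adjusted over the list alone; camera adjusted p = 0.346 with an estimated correlation), and NF-kB targets in 14 of 24 (14; adjusted p = 0.411 with an estimated correlation). 2036 genes were higher and 2198 lower (2192 and 2162 under RLE scaling), and of 8 lists called, 5 held with an estimated correlation (anti-inflammatory feedback did not, camera adjusted p = 0.192 with an estimated correlation). Ccl17 lost its call without LPS 8 h replicate 1 (edgeR adjusted p = 0.0712), 2 (0.0658), 3 (0.126) or 4 (0.101) or cell extract 8 h replicate 1 (0.135) or 3 (0.144) or without the rRNA-rich libraries (0.0933), with no filter (0.197), with DESeq2 (0.0758), under RLE scaling (0.0528) or without the shallow libraries (0.0528).

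At 24 h the difference from LPS kept that form. All 38 interferon-stimulated genes were lower with cell extract (38 adjusted over the list alone; camera adjusted p = 1.62e-43), with Tgtp1 72.9-fold lower, Gbp10 33.9-fold, Trim30b 33.6-fold, Ms4a4c 30.8-fold and Apol9b 30.8-fold. Cholesterol genes were higher in 18 of 22 cases (20; camera adjusted p = 2.91e-30). Marco was 11.4-fold higher, the collagenase Mmp8 11.4-fold, Wfdc21 13.6-fold, H19 12.4-fold and Clec4a2 10.1-fold. Nos2 was 12.7-fold lower (edgeR adjusted p = 2.29e-07) and Cxcl10 6.92-fold lower (adjusted p = 0.0114), whereas Arg1 was 3.203-fold and Mrc1 4.15-fold higher, and Ccl17 was lower (adjusted p = 0.0114). Il1b, Il6, Tnf and Il12b did not pass the test (log2 -1.13, 0.11, -0.99 and -1.23), and nor did Chil3 or Retnla (log2 0.83 and 1.08, or -0.20 and -0.54 without cell extract 24 h replicate 4). At similar folds Il1b, Tnf and Il12b passed in these groups alone (edgeR adjusted p = 7.46e-05, 0.000143 and 0.00983), and with no filter these, Chil3 and Retnla passed (at most 0.00402). 1172 genes were higher and 1274 lower. Of the 16 lists called, 7 were higher and 9 lower, and 6 held with an estimated correlation: interferon-stimulated genes, MHC class I and class II (lower), and cholesterol synthesis, oxidative stress response and neutrophil markers (higher). The M1 list (camera adjusted p = 0.173 with an estimated correlation) and the NF-kB list (0.25) were among those that did not. Cxcl10 lost its call without cell extract 24 h replicate 2 (edgeR adjusted p = 0.0867) or 4 (0.0667), and Ccl17 without LPS 24 h replicate 3 (0.203) or cell extract 24 h replicate 2 (0.0525) or without the rRNA-rich libraries (0.213). A call was gained for Il12b without cell extract 24 h replicate 3 (edgeR adjusted p = 0.0254).

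By 72 h, MHC class II genes were lower with cell extract than with LPS in 9 of 11 cases (10 adjusted over the list alone; camera adjusted p = 5.31e-16), and MHC class I genes in 16 of 17 (17). Interferon-stimulated genes were lower in 31 of 38 (32; camera adjusted p = 0.0511 with an estimated correlation). Clearance of dead cells was higher, in that 12 of 19 rose and 2 fell (12 and 2; camera adjusted p = 5.28e-09). Slc13a3 was 64.3-fold higher, 4930438A08Rik 30.8-fold, Igfbp3 12.9-fold, Marco 11.4-fold and the fatty acid transporter Slc27a6 11.1-fold. Stfa3 was 72.9-fold lower, the receptor Trem1 46.1-fold, Ly6i 38.5-fold and Ubd 30.5-fold, and Fcnb stood at 0.0153 ± 0.0265 against 2.61 ± 0.487 CPM (1 count with cell extract). Nos2 was 11.9-fold lower (edgeR adjusted p = 5.19e-07) and Il1b 11.5-fold lower (adjusted p = 0.000516), while Arg1 was 3.096-fold and Mrc1 4.57-fold higher. Ccl17 had 0 counts with cell extract and 5 with LPS (edgeR adjusted p = 0.0284). Il6, Tnf, Il12b, Cxcl10, Chil3 and Retnla did not pass the test (log2 -0.93, -1.32, -1.11, -1.42, -1.14 and -1.29). At similar folds Cxcl10, Il6, Il12b and Tnf passed in these groups alone (edgeR adjusted p = 0.00442, 0.013, 0.0298 and 0.0471), Tnf also with the block (0.0357), and with no filter all 6 passed (at most 0.00225). Cholesterol genes were not called as a list (3 of 22 higher and 3 lower, or 6 and 3 adjusted over the list alone; camera adjusted p = 0.513). 1604 genes were higher and 1651 lower, and of 12 lists called, 6 held with an estimated correlation. Ccl17 lost its call without LPS 72 h replicate 2 (edgeR adjusted p = 0.0526) or 4 (0.0605) or cell extract 72 h replicate 2 (0.147) or 4 (0.0779) or with the block (0.0519), with no filter (0.085) or with DESeq2 (0.0804).

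Across the 14537 genes, the log2 fold changes of cell extract and LPS correlated with a Pearson r of 0.657 at 8 h, 0.804 at 24 h and 0.802 at 72 h, where genes are not independent replicates and both stimuli share control libraries. Simulated unchanged groups against such controls gave 0.468, 0.474 and 0.634 on average. The covariances were 0.792, 1.03 and 1.15, exceeding the simulated ones by 0.735, 0.955 and 0.989. With separate controls for each stimulus, r was 0.472 at 8 h and 0.586 at 24 h, and at 72 h the 3 controls cannot be split, so part of the excess may come from the shared controls. For cell extract and IL-4, r was 0.101, 0.299 and 0.628, against 0.433, 0.467 and 0.641 in simulated groups, with covariances of 0.0674, 0.201 and 0.684 that exceed the simulated ones by 0.00963, 0.126 and 0.522. With split controls r was -0.0847 at 8 h and 0.00244 at 24 h.

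Genes called higher with both cell extract and LPS numbered 1413 at 8 h, 1418 at 24 h and 1333 at 72 h, where independent lists of these sizes would share 403.3, 316.3 and 331.8. Genes called lower with both numbered 1876, 1288 and 1151, against 601.5, 291.6 and 271.6. With split controls, 1034 and 1390 were shared at 8 h and 1061 and 922.3 at 24 h, as means over splits. Cell extract and IL-4 shared 195, 225 and 1081 genes higher, against 81.2, 80.6 and 271.0 for independent lists, and 277, 285 and 947 lower, against 100.7, 71.8 and 185.8. With split controls these were 105 and 144.8 at 8 h and 110.5 and 133.8 at 24 h. Genes higher with cell extract and lower with IL-4 numbered 99, 109 and 61, against 76.4, 80.9 and 216.2 for independent lists, and the reverse 163, 83 and 50, against 107.1, 71.5 and 232.9. Independent lists leave out the shared controls, so part of each excess may come from these, which cannot be split at 72 h. Simulated unchanged groups shared at most 0.15 calls as a mean over runs, and the split counts come from lists of other sizes and have no expectation of their own.

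Control cultures themselves changed between 8 h and 72 h (n = 3 at 72 h). Markers of mesothelial cells and fibroblasts rose in 11 of 17 cases (12 adjusted over the list alone; camera adjusted p = 6.64e-25), with Upk3b up 16.6-fold and the collagen gene Col1a2 6.23-fold. Sdpr rose 17.5-fold, Efemp1 16.9-fold, Ogn 16.7-fold and Igfbp2 17.8-fold, and of the muscle list 5 of 10 rose (5 adjusted over the list alone), with Tagln up 6.97-fold and Acta2 3.96-fold. Cholesterol genes rose in 14 of 22 cases (16 adjusted over the list alone; camera adjusted p = 9.25e-17), with Cyp51 up 2.302-fold, LXR and lipid genes in 6 of 18 (8), with the desaturase Scd1 up 11.8-fold, and cell cycle genes in 11 of 31 (14). Arg1 rose 12.1-fold (log2 3.60 ± 0.348, SE; edgeR adjusted p = 8.92e-10). MHC class I genes fell in 10 of 17 cases (10), with H2-Q6 down 5.01-fold. Of MHC class II 4 of 11 fell and 1 rose (4 and 1; camera adjusted p = 0.232 with an estimated correlation). Cd74 fell 3.63-fold. Prg4, a gene of resident peritoneal macrophages, fell 7.42-fold, AU020206 6.07-fold and Abtb2 7.22-fold, and Gpsm1 stood at 0.2599 ± 0.228 against 2.17 ± 0.401 CPM (3 counts at 72 h) and Gm13012 at 0.189 ± 0.179 against 1.93 ± 0.697 CPM (2 counts). Without control 72 h replicate 1, calls were lost for Igfbp2 (edgeR adjusted p = 0.0576), AU020206 (0.0535), Gpsm1 (0.0506), Abtb2 (0.05001) and Gm13012 (0.0667).

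The other genes named in every comparison did not pass the test between the controls: Nos2 (log2 -1.004), Il1b (-1.62), Il6 (-2.41), Tnf (-1.17), Il12b (-2.60), Cxcl10 (-1.69), Chil3 (0.78), Retnla (0.08), Mrc1 (0.63) and Ccl17 (8 counts at 8 h and 0 at 72 h). The first 6 stood at 0.29, 0.92, 1.08, 0.67, 0.09 and 1.53 without control 8 h replicate 1, none passing. Mrc1 passed under RLE scaling (edgeR adjusted p = 0.039), in these groups alone (0.0207), without the shallow libraries (0.038) and with DESeq2 (0.0258). With no filter Nos2, Il1b, Il6, Tnf, Il12b, Cxcl10 and Chil3 passed (edgeR adjusted p at most 0.0454). 927 genes rose and 1041 fell. Under RLE scaling 1140 rose and 638 fell, and a fit of these groups alone called 1051 genes (715 higher and 336 lower). Without control 72 h replicate 1 the count was 851, without control 8 h replicate 1 it was 1238 and without control 8 h replicate 2 it was 1254. Of 11 lists called, 7 rose and 4 fell, and 6 held with an estimated correlation, the others lost being the M2 list (camera adjusted p = 0.105 with an estimated correlation), chemokines (0.399), interferon-stimulated genes (0.61) and Toll-like receptor signalling (0.47). Il6 passed without control 8 h replicate 3 (edgeR adjusted p = 0.0498).

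The effect of cell extract differed between 72 h and 8 h in 3180 genes, 1908 with a higher and 1272 with a lower log2 change at 72 h. Cholesterol genes had a lower change at 72 h in 19 of 22 cases (20 adjusted over the list alone; camera adjusted p = 1.93e-39), NF-kB targets in 20 of 24 (22; adjusted p = 1.31e-16). Chemokines did so in 7 of 14 (7), with Cxcl1 lower by a log2 difference of -6.78 and Ccl9 -5.39. Interferon-stimulated genes had a higher change in 28 of 38 cases (28; camera adjusted p = 2.09e-09, or 0.276 with an estimated correlation). Gm14446 (5.73 ± 0.968, SE; edgeR adjusted p = 2.66e-05), 4930438A08Rik (5.33), Slc27a6 (5.27), Hsd11b1 (1 count in control at 72 h) and Clec9a (2 counts with cell extract at 8 h) also had higher changes. Upk3b (-7.24), Adm (-6.41) and Nkain4 (1 count with cell extract at 72 h) had lower ones. Arg1 (2.36; edgeR adjusted p = 0.000336), Nos2 (2.29) and Cxcl10 (3.36) had a higher change at 72 h, and Tnf (-3.54), Il1b (-3.25) and Mrc1 (-1.02) a lower one. Il6, Il12b, Chil3 and Retnla did not pass the test (-1.54, -1.28, -1.05 and -1.63), and Ccl17 had no read at 72 h. In these groups alone Retnla passed (edgeR adjusted p = 0.0344), and with no filter Il6, Chil3 and Retnla passed (at most 0.0429). Under RLE scaling 1491 differences were positive and 1606 negative. Of 12 lists called, 7 held with an estimated correlation, and MHC class I (camera adjusted p = 0.279 with an estimated correlation), glycolysis (0.196), oxidative stress response (0.073) and heat shock (0.22) did not. Without control 8 h replicate 1 the differences of Tnf, Il1b, Il6 and Il12b were -5.39, -5.80, -5.02 and -3.98, and those of Nos2 and Cxcl10 0.999 and 0.138. Nos2 lost its call without control 8 h replicate 1 (edgeR adjusted p = 0.274) or cell extract 8 h replicate 3 (0.056) or control 72 h replicate 1 (0.147) or 3 (0.0501) or cell extract 72 h replicate 4 (0.0621), and Il1b without control 72 h replicate 3 (0.142) or cell extract 72 h replicate 2 (0.0562). Nkain4 lost its call without cell extract 72 h replicate 2 (edgeR adjusted p = 0.0506), and Cxcl10 without control 8 h replicate 1 (0.949) or cell extract 8 h replicate 2 (0.0523), 3 (0.0632) or 4 (0.0547) or control 72 h replicate 1 (0.115), 3 (0.0549) or 4 (0.0636) or cell extract 72 h replicate 4 (0.0972). Mrc1 lost its call without cell extract 8 h replicate 3 (edgeR adjusted p = 0.0585) or control 72 h replicate 1 (0.103) or cell extract 72 h replicate 2 (0.0565) or 4 (0.0694). With the block calls were lost for Nos2 (edgeR adjusted p = 0.0695), Cxcl10 (0.2) and Mrc1 (0.0735), without the rRNA-rich libraries for Nos2 (0.0676), Tnf (0.0762), Il1b (0.266) and Mrc1 (0.0721) and in these groups alone for Nos2 (0.103), Il1b (0.0841) and Cxcl10 (0.12), and for Cxcl10 with DESeq2 (0.0509), under RLE scaling (0.051) and without the shallow libraries (0.052). Gained was Il6 without control 8 h replicate 1 (edgeR adjusted p = 0.000305).

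For LPS, 4354 genes differed, 2281 positively and 2073 negatively, or 1982 and 2360 under RLE scaling. Glycolysis had a higher change at 72 h in 14 of 19 genes (14 adjusted over the list alone; camera adjusted p = 5.11e-12) and MHC class II in 7 of 11 (8; adjusted p = 6.37e-06). Chemokines had a lower one in 9 of 14 (9) and cholesterol genes in 14 of 22 (14). Interferon-stimulated genes did so in 19 of 38 (21; camera adjusted p = 0.268 with an estimated correlation). Hp (log2 difference 7.06 ± 0.671, SE; edgeR adjusted p = 9.41e-11), Orm1 (7.02), Stfa3 (1 count in control at 72 h), Gm7293 and 2010005H15Rik (no read in control at 72 h, 3.14 ± 2.73 and 4.61 ± 0.4697 CPM with LPS) had higher changes. Edn1, endothelin (-7.76), Upk3b (-7.35), Adm (-6.57), Tnfsf4 (2 counts in control at 72 h) and A630012P03Rik (2 counts with LPS and 1 in control at 72 h) had lower ones. Il6 (-4.44; edgeR adjusted p = 0.0107), Tnf (-2.95) and Mrc1 (-3.11) also had a lower change at 72 h, and Nos2, Il1b, Il12b, Cxcl10, Arg1, Chil3, Retnla and Ccl17 did not pass the test (0.82, -0.62, -2.62, -2.45, 0.39, -0.07 and -0.61 in order, and for Ccl17 no read in control at 72 h). With no filter Il12b (edgeR adjusted p = 0.0167) and Cxcl10 (6.34e-11) passed, Cxcl10 also with the block (0.0222). Of 15 lists called, 8 held with an estimated correlation. The differences of Tnf, Il6 and Nos2 were -4.80, -7.92 and -0.47 without control 8 h replicate 1. With the block calls were lost for 2010005H15Rik (edgeR adjusted p = 0.0694), without the rRNA-rich libraries for 2010005H15Rik (0.0613), Tnf (0.0738), Il6 (0.157), Tnfsf4 (0.931) and A630012P03Rik (0.969) and with no filter for A630012P03Rik (0.0533). 2010005H15Rik lost its call without control 8 h replicate 2 (edgeR adjusted p = 0.106) or 4 (0.0516) or control 72 h replicate 1 (0.0626). Without control 72 h replicate 3, calls were lost for Tnf (edgeR adjusted p = 0.051), Il6 (0.123), Tnfsf4 (0.947) and A630012P03Rik (0.974). Gained calls without control 8 h replicate 1 were Il1b (-3.16, edgeR adjusted p = 0.00133), Il12b (-5.31, 0.0105) and Cxcl10 (-5.67, 3.88e-06).

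For IL-4, 2338 genes differed, 1383 positively and 955 negatively, or 921 and 1291 under RLE scaling. Cholesterol genes had a lower change at 72 h in 16 of 22 cases (18 adjusted over the list alone; camera adjusted p = 6.35e-19) and cell cycle genes in 13 of 31 (15; adjusted p = 2.23e-07). The summed cholesterol list rose in control (1051 to 1662 CPM), as did mesothelial and fibroblast markers (239 to 1158), and fell with IL-4 (893 to 663). Chil3 had a higher change at 72 h (log2 difference 3.44 ± 0.802, SE; edgeR adjusted p = 0.00279) and Arg1 a lower one (-3.14 ± 0.473; adjusted p = 1e-05). Gprc6a and Pgm5 (no read in control at 72 h, 10.1 ± 1.95 and 2.72 ± 1.65 CPM with IL-4), Slc7a3 and Arg2 (1 count each in control at 72 h) and 4930438A08Rik (3 counts with IL-4 at 8 h) had higher changes. Sdpr (-4.94), Angptl7 (-4.69), Pcdhb4 (-8.21), Apol7c (0 counts with IL-4 at 72 h) and Mrgprg (2 counts in control at 72 h) had lower ones. Retnla (2.79; edgeR adjusted p = 0.0607), Nos2, Il1b, Il6, Tnf, Il12b, Cxcl10, Mrc1 and Ccl17 did not pass the test (0.50, 0.32, 0.82, 1.31, 1.38, -0.02 and 0.02 in order, and for Ccl17 no read in control at 72 h). With no filter Tnf (edgeR adjusted p = 0.00108) and Retnla (1.38e-16) passed. Of 9 lists called, 1 upward and 8 downward, 5 held with an estimated correlation. Of the M2 list, among the 4 that did not, 10 of 30 fell and 2 rose (10 and 4; camera adjusted p = 0.0897 with an estimated correlation). Gprc6a lost its call without control 8 h replicate 2 (edgeR adjusted p = 0.0521), and Pgm5 without control 72 h replicate 1 (0.0605). Arg2 lost its call without control 72 h replicate 1 (edgeR adjusted p = 0.0648) or IL-4 72 h replicate 3 (0.0717), and Pcdhb4 without control 72 h replicate 1 (0.255). With the block calls were lost for Pgm5 (edgeR adjusted p = 0.0955) and Arg2 (0.0818) and in these groups alone for Arg2 (0.0776). Gained calls were Cxcl10 without control 8 h replicate 1 (edgeR adjusted p = 0.0256) and Retnla without control 72 h replicate 3 (0.0403) or IL-4 72 h replicate 3 (0.00259), and without IL-4 8 h replicate 3 the difference of Pcdhb4 was -5.39. With control 8 h replicate 1 left out, those of Nos2, Il1b, Il6, Tnf, Il12b and Cxcl10 were -0.80, -2.22, -2.67, -0.54, -1.31 and -3.24.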

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

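The explanations weighed in this part, and their tests, were chosen after the results had been seen. In 26 of 104 groups of 4 values examined, 1 library stood apart from the other 3, where chance alone gives about 1 in 20. Groups of 3 were not examined.

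Control 8 h replicate 1 held more of the inflammatory transcripts than the other 3 controls at 8 h: Nos2 24.4 CPM (others 2.93 to 5.12), Il1b 87.1 (3.65 to 4.90), Il6 101.0 (1.74 to 3.04), Tnf 96.4 (6.71 to 9.70), Il12b 12.03 (0.426 to 0.799) and Cxcl10 96.5 (2.35 to 3.20). In 80 genes of at least 50 CPM in LPS at 8 h and at least 64 times the mean of the other controls, its level was 3.00% of the LPS level in the median (quartiles 2.76% and 3.29%). The SD of the log2 share over genes was 0.266, against 3.03 in cell extract at 8 h, as a small share of LPS 8 h material in this library would give. A weak activation like that of the cell extract was not supported, since the Spearman correlation of the shares in the library and in cell extract was 0.130. Whether such material entered as cells, RNA or reads was not tested, and the library was kept.

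Other libraries stood apart as follows. Control 24 h replicate 1 had Nos2 at 6.92 CPM (others 1.12 to 1.80), Il6 at 15.3 (0.749 to 2.94), Il12b at 2.22 (0.214 to 0.519) and Cxcl10 at 15.1 (2.03 to 2.51). IL-4 24 h replicate 1 had Il1b at 30.5 CPM (2.05 to 6.03), Il6 at 19.6 (1.64 to 2.45), Tnf at 38.1 (3.62 to 6.69), Il12b at 5.45 (0.119 to 0.188), Cxcl10 at 26.1 (1.49 to 3.02) and Mrc1 at 317.0 (591.6 to 605.6). LPS 24 h replicate 3 had Cxcl10 at 411.2 CPM (905.4 to 996.7) and Arg1 at 65.1 (21.8 to 25.1), control 8 h replicate 2 had Arg1 at 12.99 (17.8 to 17.9), and IL-4 24 h replicate 2 had Nos2 at 7.21 (9.42 to 9.80). Control 8 h replicate 2 held 26.6 M counts (6.50 to 9.44 M). The share of counts on rRNA-like genes was 10.7% in control 8 h replicate 3, 9.51% in cell extract 8 h replicate 3, 9.06% in control 24 h replicate 3, 7.79% in LPS 24 h replicate 3 and 1.29% in IL-4 8 h replicate 4, against at most 1.28% in the others of these groups.

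By a test of the difference, effects differed between 72 h and 8 h, though the reshuffles could not exclude chance for any stimulus. Cell extract did so in 3180 genes, with log2 differences of 2.29 for Nos2, -3.25 for Il1b, -3.54 for Tnf, 3.36 for Cxcl10, 2.36 for Arg1 and -1.02 for Mrc1. Without control 8 h replicate 1 Cxcl10 (0.138) and Nos2 (0.999) were not called, and Il1b and Tnf were -5.80 and -5.39, so the values of these 4 depend on that library. With the block, Nos2, Cxcl10 and Mrc1 were not called. LPS did so in 4354 genes (Il6 -4.44, Tnf -2.95, Mrc1 -3.11) and IL-4 in 2338 (Chil3 3.44, and Arg1 -3.14, which rose in control).

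Mesothelial and fibroblast genes were lower at 72 h in the stimulated cultures, and 15 of 17 members were below the controls with all 3 stimuli. That count restates the fall and cannot tell a larger share of these cells in the controls from lower levels per cell. All 3 stimuli share 3 controls, with list sums of 1689, 812 and 973 CPM. After the 72 h libraries were thinned to 1103270 counts the median log2 change with cell extract was -2.24 (-2.42 before), so depth did not account for the fall. For LPS the medians were -2.70 thinned and -3.06 before, and for IL-4 -1.83 and -1.74.

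Interferon-stimulated genes rose less with cell extract than with LPS at 8 h, 15 of 38 rising, or 23 without control 8 h replicate 1. The median ratio of cell extract to LPS log2 changes was 0.0603 for that list and 0.823 for the NF-kB list, a difference of -0.763 (95% bootstrap interval over genes -0.891 to -0.587, 10000 resamples), so a response that was weaker by 1 factor throughout was not supported. Without control 8 h replicate 1 the median log2 change of the interferon list was 0.810, against 2.39 for the NF-kB list, and the ratios were 0.148 and 0.839. Transcripts in that library may thus hide part of the rise, and the test did not settle how much.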

How the results depend on the processing

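All 16 counts of genes called stayed within 1.5 times the reported count with RLE size factors, no filter, the block and DESeq2. They also did without the rRNA-rich or shallow libraries, both chosen after seeing the data. The reported fits were unpaired. The block gave 5008 genes for cell extract at 8 h and 7220 and 6140 for LPS at 8 and 24 h. Fits of only the groups compared gave 2787 genes for LPS at 72 h, 615 for IL-4 at 8 h, 814 for IL-4 at 24 h, 4282 for cell extract against LPS at 24 h, 1051 for control 72 h against 8 h and 1367 for the IL-4 effect difference. The cause was not tested. Leave-one-out counts ranged over 3828 to 4124, 2553 to 2940 and 2805 to 3347 genes for cell extract at 8, 24 and 72 h, 6132 to 6428, 4898 to 5181 and 3733 to 5067 for LPS, and 867 to 1325, 989 to 1278 and 2690 to 2906 for IL-4. They ranged over 3812 to 4585, 1740 to 2256 and 2226 to 3157 for cell extract against LPS, 851 to 2505 for the controls, and 2477 to 3288, 3754 to 4691 and 1721 to 2812 for the effect differences of cell extract, LPS and IL-4. With an estimated correlation, lists called were 11 for cell extract at 72 h, 7 for LPS at 24 h, and 1, 5 and 6 for IL-4 at 8, 24 and 72 h. With no filter 21 lists were called for LPS at 8 h, and without the shallow libraries 11 for IL-4 at 8 h. Leave-one-out lists numbered 12 to 13, 16 to 17 and 17 to 19 for cell extract, 9 to 10, 14 to 16 and 19 to 20 for LPS, and 6 to 14, 9 to 13 and 10 to 13 for IL-4. With controls split, the correlation of cell extract and LPS was 0.472 at 8 h and 0.586 at 24 h, and that of cell extract and IL-4 turned to -0.0847 at 8 h and was 0.00244 at 24 h. With genes of at least 10 CPM they were 0.873 and 0.162 at 24 h. Leave-one-out correlations were 0.544 to 0.711, 0.745 to 0.843 and 0.684 to 0.858 for cell extract and LPS, and 0.0572 to 0.304, 0.262 to 0.355 and 0.527 to 0.747 for cell extract and IL-4. Of 413 results on named genes, 331 kept their side of the threshold under every alternative, 82 changed it under at least 1, and 1 of these also turned, Cxcl10 with cell extract at 8 h, 2.76 without control 8 h replicate 1, with leave-one-out values from -0.857 to 2.76. By setting, calls lost and gained were 2 and 1 with RLE, 5 and 43 with no filter, 7 and 2 with the block, 13 and 0 without the rRNA-rich libraries, 2 and 1 without the shallow ones, 6 and 15 with only the groups compared, 6 and 2 with DESeq2, and 77 and 17 over 3442 leave-one-out values. In the comparisons that replicate numbers pair, the block changed no named call.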

Other observations

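Inflammasome and pyroptosis genes rose with cell extract in 8 of 14 cases at 8 h (8 adjusted over the list alone; camera adjusted p = 0.000103), 7 at 24 h (7; adjusted p = 0.000736) and 6 at 72 h (6; adjusted p = 0.0347, or 0.0833 with an estimated correlation). Set against LPS they were lower with cell extract in 8 at 8 h (9 adjusted over the list alone; camera adjusted p = 0.00692), 6 at 24 h (7; adjusted p = 0.0252, or 0.0742 with an estimated correlation) and 9 at 72 h (10; adjusted p = 0.0103).

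Markers of resident macrophages (14 tested), of T and NK cells (12) and of mast cells (7) were not called as lists in any of the 16 comparisons.

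The tests in this paragraph were chosen with the results in hand, and no allowance was made for their number. Among 35 splits of the libraries compared, fitted alone, only the real split gave as many genes for cell extract at 8 h (4705, highest other 0) and 24 h (4681, 395), LPS at 8 h (6477, 0), 24 h (6342, 0) and 72 h (2787, 1436), IL-4 at 8 h (615, 0) and 24 h (814, 0). The same holds for cell extract against LPS at 8, 24 and 72 h (4798, 4282 and 2701, highest others 0, 7 and 409). In the 3 paired comparisons every other split, those that part all pairs included, gave 0 genes. For the controls 2 of 35 splits gave as many (1051, highest other 1065), so chance cannot be excluded. At 72 h the 10 splits are too few for a share under 0.05 (cell extract 3578, highest other 0, IL-4 2717 and 0, with lists 19 and 14 and 9 and 13). For lists, only the real split gave as many for cell extract at 24 h (17, highest other 15) and LPS at 24 h (16, 15) and 72 h (20, 17). Other splits did too for cell extract at 8 h (12, highest other 14, 4 of 35 splits), LPS at 8 h (9, 11, 7 splits), IL-4 at 8 h (8, 11, 4 splits) and IL-4 at 24 h (10, 12, 4 splits). For the effect differences the first 40 splits gave highest others of 2057 for cell extract (3636), 1989 for LPS (3601) and 1932 for IL-4 (1367), with 1, 1 and 2 splits as large. The 100 splits drawn afterwards, once those counts were known, gave 2057, 2780 and 1351, with 1 split each. As 2057 recurs, the cell extract draws may share splits, so they count once. For IL-4 the draws disagree.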
